A study of Mus musculus with 30 samples.

How the data were processed

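The series held 30 sequencing libraries of mouse embryonic stem (ES) cells, with 1 library in each of 30 groups. H3K4me3 was measured by ChIP-seq in 12 libraries, H3K27me3 in 4, RNA polymerase II in 1 and GFP-tagged proteins or untagged controls in 7, and RNA was sequenced in 6. Groups, genotypes, culture medium and days of all-trans retinoic acid (atRA) were taken from the labels.

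The deposited files gave read positions as intervals, 1 line per read, with no column of values; the genome build was mm9, per the submitters' processing notes. In the deposited ChIP files each interval was 200 bp long, and in the deposited RNA files each interval was 35 bp long with a strand letter. Strand was given in the H3K4me3 files of F/F, FC/FC and the double line at day 4 and in the GFP files from 2i medium, and in no other ChIP file. The aligner, its settings, the extension of ChIP reads and the treatment of repeated reads were not given in the sources used here. Totals were equal across groups of deposited files. The 4 H3K27me3 libraries each held 4722293 reads, the 6 RNA libraries each held 7531757 reads, and the 7 GFP libraries each held 6731209 reads. Of the H3K4me3 libraries, the E14 and Mll2-/- day 0 libraries also held 6731209 reads and 7 others held 5700225 reads. Equal totals mean that sequencing depth itself cannot be read from these files, and that the precision is that of the deposited reads. H3K4me3 totals ran from 4223338 to 7328696 reads, and the RNA polymerase II library held 4523617.

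Enriched windows were found in the pooled reads of the 12 H3K4me3 libraries. Reads were counted in 200 bp bins by interval midpoint and smoothed over 5 bins, and maxima at least 4000 bp apart were taken as centres. Each centre was given a window of 1000 bp on either side, 2000 bp in all, for H3K4me3, GFP and RNA polymerase II, and of 2500 bp on either side for H3K27me3. A window was kept if the pooled signal was at least 3-fold over the median of 10000 bp bins, with a Benjamini-Hochberg level of 0.01 in a one-sided Poisson test. This gave 50383 windows, of which 1172 with over 5-fold signal in an untagged control were removed, leaving 49211. The same rule applied to each undifferentiated library called a window enriched for a mark. Windows enriched for both marks were called bivalent, and those enriched for H3K4me3 without H3K27me3 were called H3K4me3-only. Classes set in F/F cells were used to score libraries compared with E14, and classes set in E14 cells to score libraries compared with F/F, so that in comparisons by class no library both set a class and was scored in it. This does not hold for F/F over E14, where E14 set the classes and was also the denominator. It also does not hold for windows described as bivalent or H3K4me3-only in both lines, whose classes come from the control libraries of both pairs. Nor does it hold for Mll2-dependent windows, which were chosen on the E14, Mll2-/-, F/F and FC/FC libraries and share those controls with later comparisons.

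Read counts were divided by the deposited reads of the library and expressed as RPM, and median log2 ratios were taken on log2(RPM + 0.5). In comparisons of 1 library with 1 library, a window counted as lower or higher at a ratio of at least 2-fold with at least 20 reads in the higher library; no p-value was computed. Ratios carry exact conditional (Clopper-Pearson) 95% intervals, which cover counting error only and say nothing about variation between cultures. Medians of window classes were placed among 10000 random lists of windows matched on mean level. These lists were drawn from all windows enriched for H3K4me3, bivalent ones included. Windows or intervals of 1 library pair are not replicates, so a rank among lists says nothing about variation between cultures. Overlaps of comparisons that shared a control were set against independent lists and against 100 simulations of unchanged groups (50 for RNA).

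Effects of Mll2 loss on H3K4me3 and H3K27me3 were also tested over both cell line pairs with limma-trend on log2(RPM + 0.5), with the pair as a block, two-sided, at a Benjamini-Hochberg level of 0.05, in windows with at least 20 reads in at least 1 library. This fit left 1 residual degree of freedom. For H3K4me3 limma estimated a total of 26700 degrees of freedom, so the calls rest on a spread shared by all windows. Fold changes on this scale understate changes at low counts. The test on counts first named for this purpose was replaced by limma because the files have no column of counts.

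RNA reads of all 6 libraries were joined across gaps of up to 1000 bp into 37528 transcribed intervals, without regard to strand, so overlapping transcripts on opposite strands cannot be told apart. Of these, 23964 had at least 20 reads in at least 1 library and were tested with limma-trend on log2(RPM + 0.5), with terms for genotype and day, leaving 2 residual degrees of freedom. An interval was assigned to a window where it held the window's centre, or lay within 2000 bp of it.

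GFP libraries were divided by the untagged control of the same medium, and a window counted as bound at 3-fold or more with at least 20 reads. The labels of the 2i libraries name serum and LIF as well, and the other GFP libraries were grown in serum and LIF without 2i. The 2i control and the Mll2 C-terminal tag library were labelled as double crosslinked, whereas the Mll2 N-terminal tag library in 2i was not.

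Each test was first tried on simulated data with 200 changed features. For H3K4me3, 59% of 2-fold and 89% of 4-fold changes were recovered with 7 false calls. That simulation held counting error only, with no further variation between libraries (SD 0), so it does not show how the test performs where libraries vary more. The others held an SD of 0.283 on the log2 scale for H3K27me3 and 0.236 for RNA. For H3K27me3 the shares were 22% and 83% with 9 false calls. For Mll2 loss in RNA they were 35% and 90% with 8 false calls, and for atRA 52% and 92% with 3 false calls.

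Comparisons, tests, thresholds and most alternatives were chosen before the data were examined. The details of finding windows and transcribed intervals (bins, smoothing, spacing, the limit on untagged controls and the gap) were set after the data had been seen. Alternatives were background scaling over 10000 bp bins below the 75th percentile, size factors over H3K4me3-only windows, median-ratio scaling, windows of 500 and 2000 bp on either side (1000 and 5000 bp for H3K27me3), minimums of 10 and 50 reads, a 3-fold rule, other enrichment thresholds, the other untagged control, repeated positions counted once, other filters, blocks and pseudocounts (0.1 and 2), limma without a trend, and leaving out a genotype, day or pair. Leaving out chromosomes 8 and 11, median-ratio scaling over H3K4me3-only windows in limma, other gaps between transcribed intervals (300 and 5000 bp), counting repeated RNA positions once, and comparing the double FC/FC library with Mll2 FC/FC were added after the data had been seen.

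Windows and intervals named in the text are up to 5 with the largest decrease and up to 5 with the largest increase among those meeting the size rule in a comparison (in both pairs, ordered by the smaller change, where there are 2 pairs), or, for the RNA tests, among calls with the same sign at both days. Windows named for another reason are said to have been chosen after their values were seen. Coordinates are 1-based mm9 positions. The annotation tables used here were of GRCm38, another build, so gene names, promoters, gene lists and cell type markers, and the reads over the targeted exons of Mll1 and Mll2, were not analysed here. The genotypes are therefore those of the labels.

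Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, R 4.3.3 with limma 3.58.1, and matplotlib 3.10.9 for the figures.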

Results

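Mll2 and Mll1 are histone methyltransferases that place methyl groups on lysine 4 of histone H3, and H3K4me3 is the trimethylated form found at active and poised promoters. H3K27me3 is a repressive mark of Polycomb complexes, and a region carrying both marks is called bivalent. The libraries came from ES cells of several lines. E14 is the wild-type line. Per the labels, Mll2-/- and Mll1-/- cells were made from E14TG2a by gene targeting, but they had reads in a stretch of chromosome X in which 5 E14 libraries had none. F/F cells carry conditional Mll2 alleles and an inducible Cre recombinase, and FC/FC cells are the same kind of line after the deletion was induced. A double FC/FC line had both Mll1 and Mll2 deleted. Cells were undifferentiated (day 0) or had been treated with atRA, which drives differentiation, for 4 or 7 days. GFP was pulled down from cells with tagged Mll2, tagged Cxxc1 or tagged Ash2l. Cxxc1 is a CpG-binding subunit of another H3K4 methyltransferase complex, and Ash2l is a subunit shared by these complexes. The 30 libraries held from 4223338 to 7531757 reads each. No group had replicates, so differences between libraries have no replicate check, and the intervals given for ratios cover counting error only. Windows and intervals are named by mm9 chromosome, start and end.

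The first question, named in the series title, was which regions need Mll2 for H3K4me3 in undifferentiated cells. At chromosome 6, 128792301 to 128794300, a bivalent window, E14 cells had 173 reads and Mll2-/- cells 19, while F/F cells had 157 and FC/FC cells 17. These are ratios of 0.110 (95% interval 0.0646 to 0.177) and 0.108 (0.0615 to 0.179). Across the genome 2182 of 15266 windows tested in both pairs (14.3%) had at least 2-fold less H3K4me3 in both knockouts, where 810.6 were expected from independent lists. In contrast, 8 windows were at least 2-fold higher in both, where 0.6 were expected. At the 2182 windows, called Mll2-dependent windows here, median H3K4me3, as the read count scaled to library size (RPM), was 11.6 in E14 and 2.82 in Mll2-/-, and 7.02 in F/F and 2.46 in FC/FC.

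H3K27me3 was present in E14 at 89.7% of the Mll2-dependent windows and at 48.6% of all windows tested. Of windows bivalent in both lines, 1921 of 6837 (28.1%) were lower in both pairs. Of windows with H3K4me3 alone in both lines, 144 of 7013 (2.05%) were. In limma over both pairs, 3293 windows fell and 119 rose of 26698 tested. Of the windows that fell, 86.6% were bivalent in both lines, against 34.1% of those tested, and their median log2 fold change was -1.41. Of the 2182 Mll2-dependent windows, 1954 (89.6%) were among the calls. The test depended on its design. Median-ratio scaling, which moved the median log2 fold change of all windows from -0.23 to 0.07, gave 1565 lower and 720 higher, so the share of lower calls went from 96.5% to 68.5%. Without the pair as a block limma called 0 windows (1466 at an unadjusted 0.05), and without the filter on low counts it also called 0 (6487 unadjusted).

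Other windows with a large decrease in both pairs were on chromosomes 3, 17, 9 and 13. The window at chromosome 3, 96204701 to 96206700, bivalent in both lines, went from 111 reads in E14 to 7 in Mll2-/- and from 69 in F/F to 7 in FC/FC. Its log2 fold change was -3.17 (SE 0.413, limma adjusted p = 2.32e-11). At chromosome 17, 23682901 to 23684900, reads went from 255 to 13 and from 119 to 15, with a log2 fold change of -3.38 (SE 0.328, limma adjusted p = 1.95e-20). At chromosome 9, 31719901 to 31721900, they went from 133 to 16 and from 56 to 6. At chromosome 13, 23544701 to 23546700, a window with H3K4me3 alone, they went from 120 to 16 and from 64 to 6. The window on chromosome 6 described above had a log2 fold change of -2.99 (SE 0.319, limma adjusted p = 7.96e-17). Of the windows that were higher in both pairs, chromosome 18, 82928701 to 82930700, had 80 reads in E14, 263 in Mll2-/-, 16 in F/F and 34 in FC/FC (limma adjusted p = 0.000657). Chromosome 11, 121006901 to 121008900, had 94, 210, 37 and 76 reads in the same order (limma adjusted p = 0.00215), a ratio of 2.23 in the E14 pair, where the whole chromosome had 1.499 times the reads per bin. Chromosome 3, 9080901 to 9082900, had 22, 67, 9 and 23 reads (limma adjusted p = 0.026). Windows at chromosome 8, 122601901 to 122603900, and chromosome 7, 29709501 to 29711500, met the size rule but did not pass limma (adjusted p = 0.202 and 0.312). Chromosome 8 also had 1.43 times the reads in Mll2-/-, and without chromosomes 8 and 11, an alternative chosen after the data were seen, 6 windows were higher in both pairs.

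**Figure D1:**
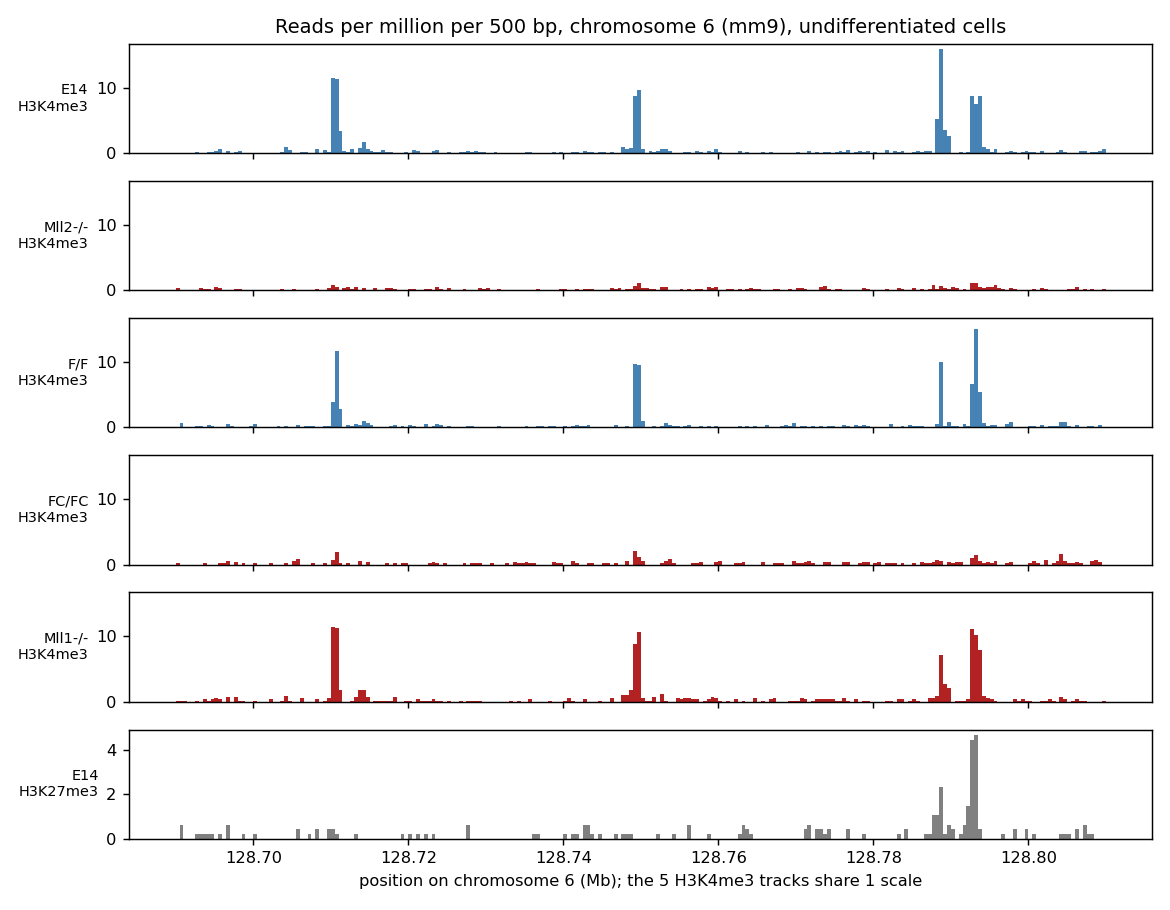
RPM in 500 bp bins (vertical axis) along a stretch of chromosome 6 (horizontal axis, Mb), 1 track per library, with E14 and F/F in blue, Mll2-/-, FC/FC and Mll1-/- in red and E14 H3K27me3 in grey. The window at 128792301 to 128794300 held 173 reads in E14, 19 in Mll2-/-, 157 in F/F, 17 in FC/FC and 169 in Mll1-/-.

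Each pair taken alone gave more windows, but libraries of lines with intact Mll2 also differed. In F/F over E14, both controls, 7824 of 24690 windows (31.7%) were at least 2-fold lower and 2023 higher, with a median log2 ratio of -0.60. In Mll2-/- over E14, 7492 of 23614 windows (31.7%) were at least 2-fold lower and 836 higher. Of the higher windows, 345 lay on chromosomes 8 and 11, where 10.0% of windows were higher, against 2.43% elsewhere. Without these chromosomes, an alternative chosen after the data were seen, 6862 windows were lower and 491 higher. In FC/FC over F/F, 3434 of 18350 (18.7%) were lower and 216 higher. Bivalent windows had a median log2 ratio of -0.60 (quartiles -1.32 to 0.0) in the E14 pair and -0.44 (-0.87 to -0.05) in the F/F pair. Windows with H3K4me3 alone had medians of 0.0 and -0.01. Both bivalent medians lay below those of all 10000 random lists of windows matched on level. Windows with H3K4me3 alone, weighted to the levels of bivalent windows, had medians of -0.10 and -0.10. The share of windows that were lower grew with H3K27me3. From the lowest to the highest quartile of H3K27me3, 8.38%, 16.1%, 34.1% and 55.9% were lower in the E14 pair, and 4.19%, 5.62%, 13.0% and 39.2% in the F/F pair. The share also varied with H3K4me3. By quartile of H3K4me3 it was 41.25%, 49.5%, 53.4% and 7.64% in the E14 pair, and 11.6%, 14.9%, 37.2% and 11.0% in the F/F pair. Neither ranking was adjusted for the other. Within the E14 pair, chromosome 13, 23608701 to 23610700, went from 146 reads to 4, a 36.5-fold decrease, and chromosome 13, 23528501 to 23530500, from 158 to 6, a 26.3-fold decrease. Chromosome 13, 21418101 to 21420100, went from 109 to 4, and chromosome X, 20665501 to 20667500, from 49 reads to 0. In the F/F pair, chromosome 14, 30534701 to 30536700, went from 42 to 3 (ratio 0.0714, interval 0.0142 to 0.224) and chromosome 8, 37520101 to 37522100, from 114 to 13. Chromosomes 8 and 11 had 1.43 and 1.499 times the reads per bin in Mll2-/- as in E14. In that pair 18.3% of their windows were lower, against 34.0% on other chromosomes.

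**Figure D2:**
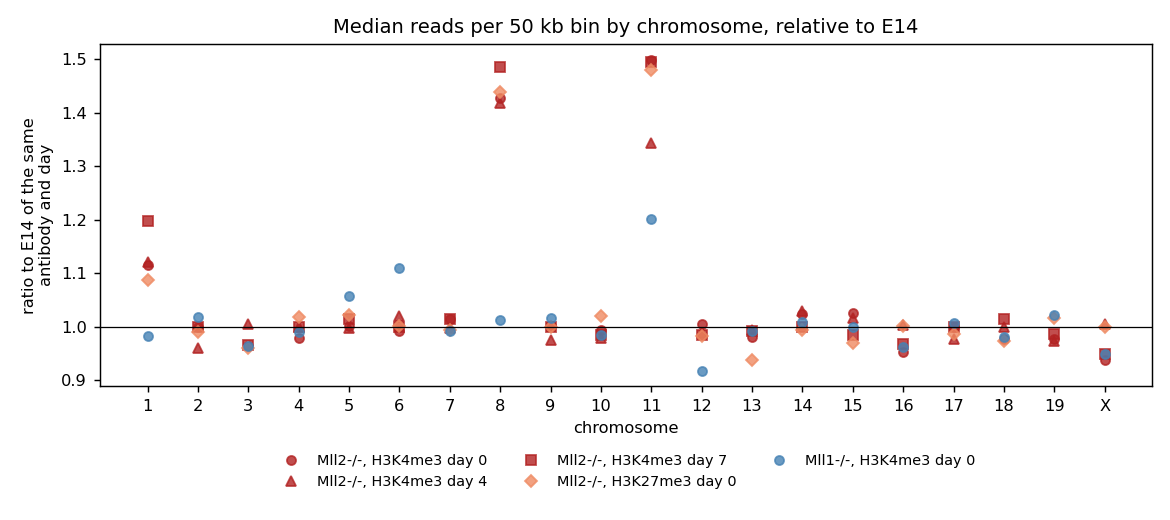
Median reads per 50 kb bin on each chromosome as a ratio to the E14 library of the same day and mark (vertical axis), with 1 symbol per library. In Mll2-/- H3K4me3 at day 0 chromosomes 8 and 11 stood at 1.43 and 1.499, while in Mll1-/- chromosome 11 stood at 1.20.

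**Figure D3:**
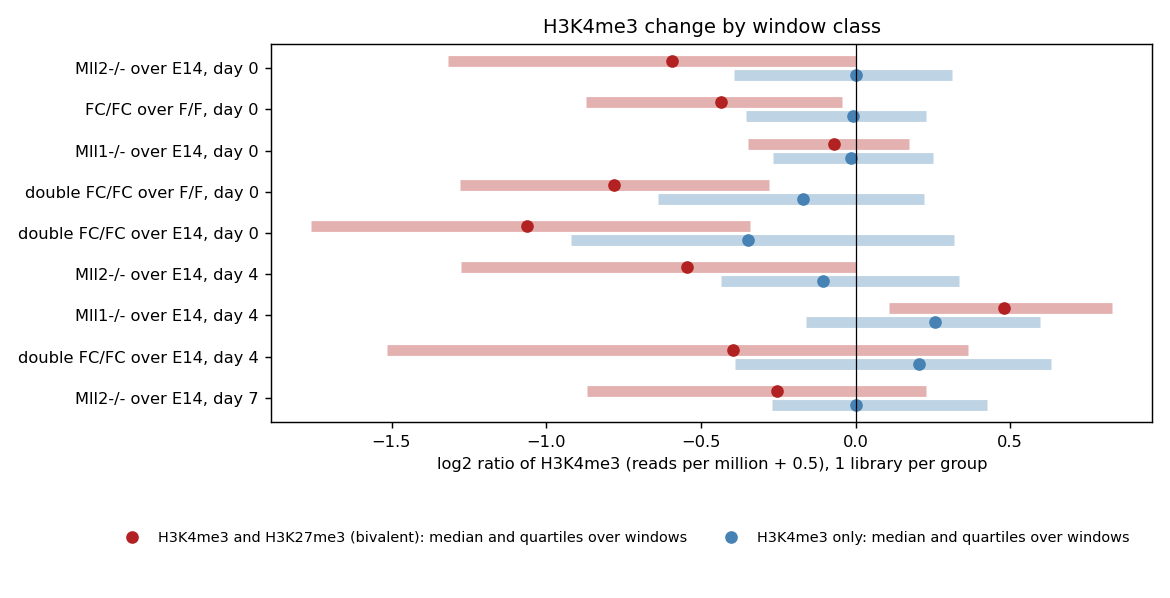
Median log2 ratio of H3K4me3 (points) with quartiles (bars) in bivalent windows and in windows with H3K4me3 alone, for 9 comparisons of a knockout with its control library. The bivalent median lay below that of H3K4me3-only windows in 8 comparisons and above it in Mll1-/- over E14 at day 4, at 0.48 against 0.26.

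Mll1 loss was compared to ask whether Mll1 is needed at the same regions. In Mll1-/- over E14, 1009 of 23258 windows (4.34%) were lower and 554 were higher. The Mll2-dependent windows had a median log2 ratio of -0.11 in Mll1-/-, with 55 of 2182 (2.52%) lower, and a median of 10.7 RPM. Bivalent windows had a median of -0.07 and windows with H3K4me3 alone one of -0.02. The bivalent median lay below those of all 10000 random lists, which ran from -0.06 to -0.04. In F/F over E14, both controls, the bivalent median of -0.475 also lay outside all lists, above their range of -0.601 to -0.558. Such a rank therefore does not by itself show an effect of Mll1 loss. Among the largest decreases was a bivalent window on chromosome 12, 110778701 to 110780700, where E14 had 145 reads and Mll1-/- had 14 (ratio 0.114, interval 0.0608 to 0.198). The same window had 240 reads in Mll2-/-, 94 in F/F and 97 in FC/FC. At chromosome 10, 105443101 to 105445100, reads went from 85 to 12. At chromosome 8, 67732501 to 67734500, they went from 21 to 0. A total of 742 windows were lower in both Mll1-/- and Mll2-/- over E14. Independent lists gave 333.7 and simulated unchanged cells sharing the E14 control gave 46.88, so part of the overlap may come from the shared control. The covariance of the log2 ratios was 0.164, against 0.0453 in the simulation, but their Pearson correlation was 0.427, below the simulated 0.525. The 2 measures point opposite ways, so a relation beyond the shared control stays open. With at least 50 reads the count of lower windows in Mll1-/- was 145, and with at least 10 reads it was 2609.

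In the double FC/FC line, 6126 of 17433 windows (35.1%) were lower than in F/F and 269 were higher. Mll2-dependent windows had a median log2 ratio of -1.53, with 1906 of 2182 (87.4%) lower. Bivalent windows had a median of -0.78 with 53.8% lower, and windows with H3K4me3 alone one of -0.17 with 14.9% lower. Over E14 the counts were 13964 lower and 253 higher of 22501, and 8968 lower with size factors over H3K4me3-only windows. These may include differences between lines or between libraries, since F/F without the deletion was lower than E14 at 7824 windows. The low-signal bins used for background scaling held 27.1% of reads in E14, 37.5% in F/F and 44.0% in the double line. With 1 library each, differences between lines and between libraries cannot be told apart. By classes set in E14, the denominator of F/F over E14, 39.4% of tested windows with H3K4me3 alone were lower in F/F. Of tested windows with H3K4me3 alone in both lines, 27.4% were. The labels gave no uninduced library of the double line, which is of another strain. Over Mll2 FC/FC, a comparison chosen after the data were seen, 1766 of 13947 windows were lower and 304 higher. There the Mll2-dependent windows had a median log2 ratio of -0.14, with 61 of 617 lower and 32 higher. These windows were chosen as low in FC/FC, the denominator here, with a median of 2.46 RPM. Most of the 2182 had too few reads to be tested, so these values do not show whether Mll1 loss adds an effect. At chromosome 5, 139063501 to 139065500, the double line had 0 reads, while F/F had 29, FC/FC 22 and E14 83, but the double line had 209 reads there at day 4 of atRA. At chromosome 2, 124435301 to 124437300, it had 1 read against 54 in F/F (ratio 0.02499, interval 0.000621 to 0.145), and 223 at day 4. Windows lower in both the double and the Mll2 FC/FC line over F/F numbered 2780, where independent lists gave 1219.4 and simulated unchanged cells 75.27, so part of that overlap may come from the shared control. The covariance was 0.289, against 0.0631 simulated.

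The next question was whether regions low in H3K4me3 without Mll2 stayed low when cells differentiated. At day 4 of atRA, 4753 of 15211 windows (31.2%) were lower in Mll2-/- than in E14 and 361 were higher, and at day 7 the counts were 2962 of 13809 (21.4%) and 535. The Mll2-dependent windows of day 0 had median log2 ratios of -1.70 at day 4 and -1.29 at day 7, with 1537 of 1863 (82.5%) and 1219 of 1661 (73.4%) lower. These shares leave out windows with fewer than 20 reads in both libraries. Median H3K4me3 at the 2182 windows was 11.6, 11.1 and 8.95 RPM in E14 at days 0, 4 and 7. In Mll2-/- it was 2.82, 2.1 and 1.93. The smaller ratio at day 7 thus went with a lower E14 level, while the Mll2-/- median did not rise. Bivalent windows had median log2 ratios of -0.54 at day 4 and -0.26 at day 7, and windows with H3K4me3 alone -0.11 and 0.0. At chromosome 6, 128788101 to 128790100, reads went from 347 in E14 to 6 in Mll2-/- at day 4 and from 299 to 5 at day 7. Several windows on chromosome 13 were also among the largest decreases. Chromosome 13, 21366901 to 21368900, had 276 reads in E14 and 4 in Mll2-/- at day 4, and 245 and 5 at day 7. Chromosome 13, 22112701 to 22114700, had 378 and 6 at day 4. Chromosome 13, 23390501 to 23392500, had 264 and 4 at day 4, and chromosome 13, 23528501 to 23530500, had 221 and 2 at day 7 (ratio 0.00905, interval 0.00109 to 0.0331). In the other direction, chromosome 1, 58271501 to 58273500, had 2 reads in E14 and 173 in Mll2-/- at day 4, and 10 and 189 at day 7. Chromosome 4, 138261901 to 138263900, had 6 and 167 reads at day 7. Of 789 windows that gained H3K4me3 at least 2-fold in E14 between day 0 and day 7, 74.9% carried H3K27me3 in E14 at day 0, and 597 gained at least 2-fold in Mll2-/- as well. These gains started from a lower level, with a median log2 ratio to E14 of -0.71 at day 0 and 302 of 607 windows lower. At day 7 the median was -0.39, with 182 of 789 lower. The 789 windows were chosen on the E14 libraries, which are also the controls here. In Mll2-/- 1386 windows gained and 6226 lost at least 2-fold over these days, while 9609 lost in E14.

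Mll1-/- cells at day 4 had more windows above than below E14, with 2616 higher and 139 lower of 16162. The Mll2-dependent windows had a median log2 ratio of 0.62 in this comparison, with 414 of 1976 higher and 6 lower, beside a median of all windows of 0.50. This balance moved with scaling. With size factors over H3K4me3-only windows there were 306 lower and 1035 higher, so the lower share of changed windows went from 5.05% to 22.8%, and with background scaling there were 34 lower and 11551 higher. The largest decreases included chromosome 6, 97302701 to 97304700, with 69 reads in E14 and 4 in Mll1-/-, and chromosome 12, 110778701 to 110780700, with 199 and 19. Chromosome 8, 124065101 to 124067100, had 3 reads in E14 and 74 in Mll1-/- (ratio 29.4, interval 9.67 to 145.7). Windows lower in both knockouts over E14 at day 4 numbered 59, where independent lists gave 44.2 and simulated unchanged cells 30.87. The covariance was 0.0197, against 0.0573 simulated.

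The double line at day 4 was compared with E14, but whether this library came from the same line as the double library of day 0 is open. It had 27 reads on chromosome Y, against 847 at day 0, and a ratio of chromosome X to autosomes of 0.259, against 0.431. The differences from E14 given here can therefore not be assigned to the deletions alone. In this library 5043 of 15929 windows (31.7%) were lower than in E14 and 2418 were higher. Bivalent windows had a median log2 ratio of -0.40 and windows with H3K4me3 alone one of 0.20, and the Mll2-dependent windows had a median of -2.20 with 83.2% lower. The share of lower among changed windows, 67.6%, was 82.8% with size factors over H3K4me3-only windows (5820 lower, 1212 higher) and 47.6% with background scaling (4469 lower, 4917 higher). At chromosome Y, 346501 to 348500, E14 had 241 reads and the double line 0, but that library had 27 reads on the whole of chromosome Y, against 2073 in E14. At chromosome 3, 96076901 to 96078900, they had 201 and 1. Chromosome 10, 61988501 to 61990500, had 3 reads in E14 and 769 in the double line, and chromosome 5, 65739101 to 65741100, had 1 and 595. The same windows had 91 and 81 reads in E14 at day 7.

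H3K27me3 was compared to ask whether it changed where H3K4me3 was lost. The 2 pairs did not move together. In the E14 pair, Mll2-dependent windows had a median log2 ratio of 0.05, with 97 higher and 28 lower of 2027, and in the F/F pair one of 0.41, with 430 higher and 92 lower of 2007. Median H3K27me3 at these windows was 25.4 RPM in E14, 27.1 in Mll2-/-, 20.8 in F/F and 26.9 in FC/FC. Bivalent windows lower in H3K4me3 in neither pair had median log2 ratios of 0.13 and -0.07. Across 15228 windows, 24 were higher in both pairs and 54 lower in both, where 154.88 and 61.03 were expected, and Spearman's rho across windows, which are not independent replicates, was -0.28. The limma test over both pairs called 0 of 20911 windows, with 133 at an unadjusted 0.05.

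GFP ChIP showed where the tagged proteins were found. A window counted as bound at 3-fold over the untagged control with at least 20 reads. N-terminally tagged Mll2 in serum bound 15960 of 49211 windows, Cxxc1 12486 and Ash2l 16628. C-terminally tagged Mll2 in 2i, which stands here for medium with serum, LIF and kinase inhibitors, bound 19303, and N-terminally tagged Mll2 in 2i 3513. Mll2-dependent windows were bound by N-terminally tagged Mll2 in 79.8% of cases, by C-terminally tagged Mll2 in 93.5%, by Cxxc1 in 38.9% and by Ash2l in 38.2%. Bivalent windows that were lower in neither pair were bound in 77.2%, 93.8%, 71.0% and 62.7%, and windows with H3K4me3 alone in 40.2%, 53.7%, 45.8% and 53.5%. For N-terminally tagged Mll2 in 2i the shares of these 3 sets were 20.9%, 22.2% and 9.87%, but its control was labelled as double crosslinked and the library was not. Bound shares also depend on the minimum of 20 reads. Median folds over control at Mll2-dependent windows were 4.91 for N-terminally tagged Mll2 in serum, 3.04 for Cxxc1 and 3.05 for Ash2l. For Cxxc1 and Ash2l the median thus passed 3-fold, though only 38.9% and 38.2% were called bound. At bivalent windows lower in neither pair the median folds were 4.46, 4.35 and 3.715. The sets differ in H3K4me3 level, with medians of 11.6 RPM in E14 at Mll2-dependent windows and 22.1 at bivalent windows lower in neither pair. Against level-matched windows of the latter kind, bivalent Mll2-dependent windows had median log2 enrichments of 1.64 and 1.76 for Cxxc1, 1.61 and 1.73 for Ash2l, and 2.35 and 2.03 for N-terminally tagged Mll2 in serum. The N-terminal tag in serum and the C-terminal tag in 2i, with different controls, shared 12828 windows, where 6260.3 were expected from independent lists. All bound calls rest on 1 untagged control each. The serum control listed 2251008 positions exactly 2 times, and the 2i control had 87 reads on chromosome Y and a ratio of chromosome X to autosomes of 0.823. Against the other untagged control the count for N-terminally tagged Mll2 in serum was 8090, for Cxxc1 7963 and for Ash2l 8512, while for N-terminally tagged Mll2 in 2i it was 10155. RNA polymerase II in E14 had a median log2 enrichment over background of 3.21 at Mll2-dependent bivalent windows and 4.33 at level-matched bivalent windows that were lower in neither pair. Across 6837 bivalent windows, which are not independent replicates, the log2 ratio of Mll2 loss had a Spearman's rho of 0.53 with RNA polymerase II and -0.37 with H3K27me3. It was 0.37 with the level of H3K4me3 in Mll1-/- cells, and none of these relations was adjusted for level. With Cxxc1 it was 0.27 and with Ash2l 0.16. For Mll2 it was -0.12 with the N-terminal tag in serum, -0.03 with the N-terminal tag in 2i and 0.02 with the C-terminal tag in 2i.

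**Figure D4:**
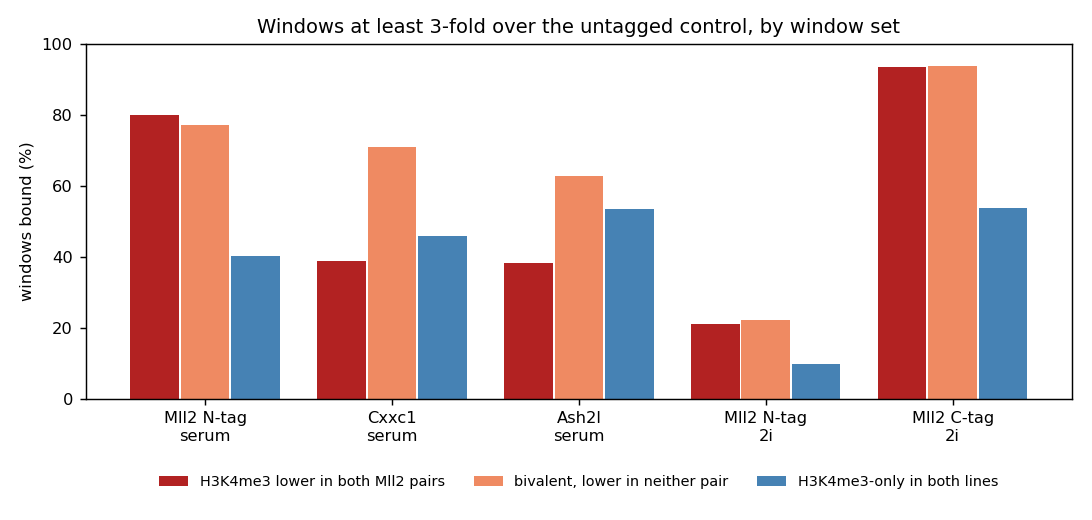
Percentage of windows bound (bars, from 0) for 5 GFP-tagged libraries and several sets of windows. Bound means at least 3-fold over the untagged control of the same medium, with at least 20 reads. In Mll2-dependent windows the bars stand at 79.8% for N-terminally tagged Mll2 in serum, 38.9% for Cxxc1 and 38.2% for Ash2l.

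RNA was compared to ask which transcripts changed without Mll2. In limma over both days, 6 of 23964 transcribed intervals fell and 3 rose in Mll2-/- (3688 at an unadjusted 0.05). Chromosome 5, 150561229 to 150565171, fell by 4.42 on the log2 scale (SE 0.379, limma adjusted p = 0.0279), from 68 reads in E14 to 1 in Mll2-/- at day 0 and from 171 to 2 at day 4. The interval starting at chromosome 5, 109976374, which lay near an Mll2-dependent window, had a log2 fold change of -3.64 (limma adjusted p = 0.0377), with 95 reads against 4 and 115 against 6. Intervals starting at chromosome 3, 144796935, chromosome 8, 72226296, and chromosome 7, 149834309, fell by 3.59, 2.64 and 2.63. An interval on chromosome 17 starting at 39979942 rose by 1.80 (limma adjusted p = 0.0279), and another on chromosome 4 starting at 3900248 by 1.70. The other call that rose, on chromosome X from 50348393 to 50375866 with a log2 fold change of 4.03, overlapped a stretch in which the E14 libraries for H3K4me3, H3K27me3 and RNA polymerase II had no reads. The count of calls was 0 in limma without a trend (3217 unadjusted) and 415 with intervals joined over 300 bp. For each day alone, 2605 of 19469 intervals were at least 2-fold lower and 2348 higher at day 0, and 1340 of 19130 lower and 2007 higher at day 4. Of the intervals tested at both days, 374 were lower on both, where 69.18 were expected, and 486 higher on both, where 148.83 were expected. Many changes were shared with Mll1-/-, which was compared with the same E14 libraries. At day 0, 1377 intervals were lower and 515 higher in both knockouts, where 306.62 and 69.73 were expected. At day 4 these were 616 and 930, where 129.57 and 166.43 were expected. Part of the changes may therefore come from the shared control and not from Mll2 loss.

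**Figure D5:**
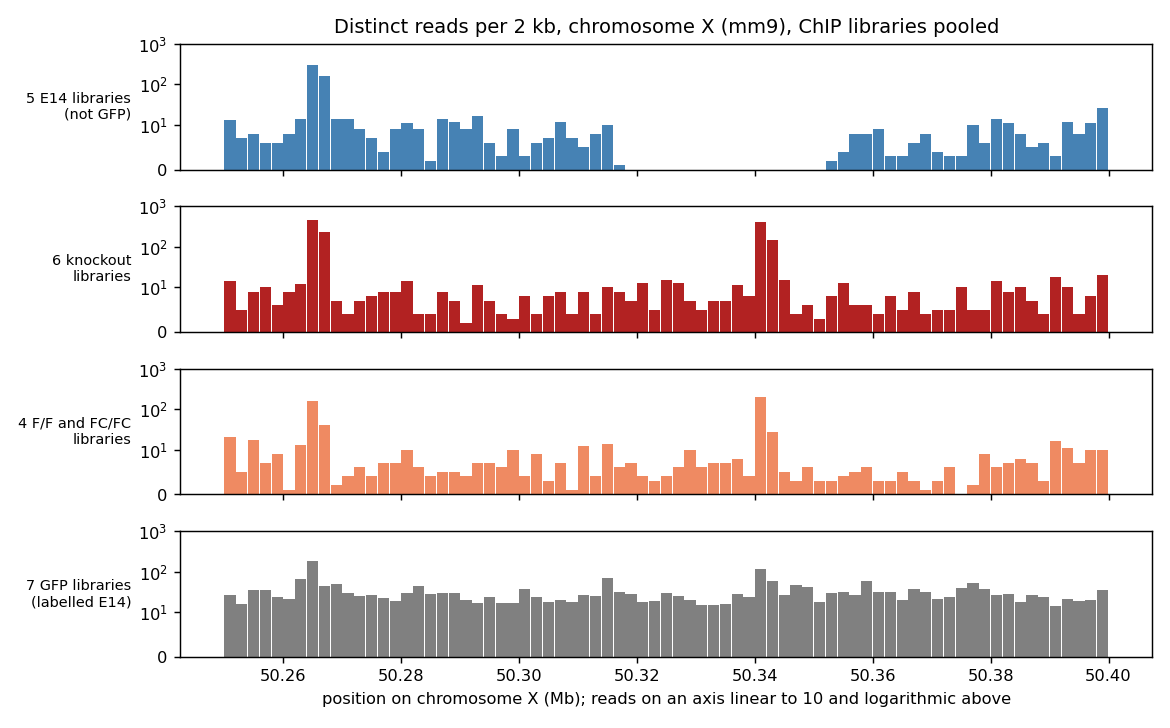
Distinct reads per 2000 bp bin (symmetric log axis) along chromosome X around 50318001 to 50352000, for 4 pooled sets of libraries. The 34 kb stretch held 0 reads in the 5 E14 libraries for H3K4me3, H3K27me3 and RNA polymerase II, 674 in 6 Mll2-/- and Mll1-/- ChIP libraries, and 38 to 114 in each of the 7 GFP libraries, which are also labelled E14.

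The 596 intervals near Mll2-dependent windows had a median log2 RNA ratio of -0.11 in Mll2-/- at day 0, at percentile 0.01 of 10000 random lists matched on expression, and of 0.0 at day 4, at percentile 1.55. In Mll1-/- the medians were -0.12 and -0.04, both below all random lists. Intervals near bivalent windows outside this set had medians of 0.17 and 0.17 in Mll2-/- on these days. With windows at least 3-fold lower in both pairs the medians in Mll2-/- were -0.40 and -0.22, and with intervals joined over 300 bp the day 0 median was 0.0. On chromosomes 8 and 11, which hold 8.52% Mll2-dependent windows among those tested, against 15.3% elsewhere, all intervals had median RNA ratios of 0.51 and 0.57 in Mll2-/- at day 0. Without these chromosomes, an alternative chosen after the data were seen, the 532 intervals near Mll2-dependent windows had medians of -0.18 and -0.03, at percentiles 0.01 and 0.73. Intervals near other bivalent windows then had 0.08 and 0.09. In Mll1-/- all intervals on chromosome 11 had medians of 0.25 and 0.43, and without both chromosomes the medians near Mll2-dependent windows were -0.15 and -0.07, again below all random lists.

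In Mll1-/-, 5 of 23964 intervals fell and 1 rose in limma (2731 at an unadjusted 0.05). Of those that fell, 3 lay close together on chromosome 12. The interval from 110778742 to 110859648 had 5290 reads in E14 and 162 in Mll1-/- at day 0, and 21576 and 1720 at day 4, with a log2 fold change of -4.32 (SE 0.281, limma adjusted p = 0.00268). In Mll2-/- it had 5195 and 36016 reads. It overlapped the bivalent window whose H3K4me3 was lower in Mll1-/-. The neighbouring intervals starting at 110861003 and 110957880 fell by 3.98 and 4.02. On chromosome X, the interval starting at 61749236 fell by 3.80 (limma adjusted p = 0.00261), and the one starting at 86005374 went from 83 reads to 1 at day 0 and from 325 to 19 at day 4. The interval that rose was the same as in Mll2-/-, on chromosome X at 50348393, with a log2 fold change of 4.31. The Mll1 and Mll2 tests shared this 1 call and the E14 control libraries. The covariance of their log2 fold changes was 0.2498, against 0.0465 in simulated unchanged cells.

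Treatment with atRA was compared to show the change on differentiation in E14, Mll1-/- and Mll2-/- cells. In limma 3589 intervals fell and 4918 rose between day 0 and day 4 (11305 at an unadjusted 0.05). With median-ratio scaling 4270 fell and 4291 rose, so the excess of rises depended on scaling. An interval on chromosome 7 starting at 77490912 went from 56 to 2181 reads in E14, from 9 to 460 in Mll1-/- and from 6 to 1006 in Mll2-/-, with a log2 fold change of 5.69 (SE 0.327, limma adjusted p = 0.000179). Intervals on chromosome 6 starting at 36691078 and 36663802 went from 5 to 778 and from 44 to 1853 reads in E14, and one on chromosome 13 starting at 78328232 from 20 to 1032. An interval on chromosome 8 starting at 80596082 fell from 615 reads to 2 in E14, with a log2 fold change of -5.05. Of the 596 intervals near Mll2-dependent windows, 230 (38.6%) rose with atRA, against 33.3% of the 3420 intervals near bivalent windows and 20.5% of all intervals. Without the Mll2-/- libraries the count of calls was 4292.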

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

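The tests of the chromosome X stretch, and those of bivalent windows and of FC/FC cells on chromosomes 8 and 11, were chosen after the result was seen, as were those of medians and shares of thinned reads; the tests with chromosome ratios, background and the count of lower windows after thinning were chosen before.

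A stretch of 34 kb on chromosome X, 50318001 to 50352000, held 0 reads in the 5 E14 libraries for H3K4me3, H3K27me3 and RNA polymerase II and 674 reads in 6 Mll2-/- and Mll1-/- ChIP libraries. Too few reads are argued against, since 466.3 were expected in 4 of the E14 libraries at the density of the knockout libraries, and so are unreadable or filtered bases, since 19 of the 19 other ChIP libraries had reads there. These 19 include the 7 GFP libraries, also labelled E14, with 38 to 114 reads each, which argues against a stretch missing from all cells labelled E14. The highest RNA count there was 3 in an E14 library and the lowest was 21 in a knockout library, so a stretch missing from the cells of the E14 libraries other than GFP may account for the pattern. The labels name E14 for both sets of libraries and E14TG2a as the parent of the knockouts, so which cells were used for each stays open, and no biological explanation was tested.

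Chromosomes 8 and 11 had 1.43 and 1.499 times the reads per bin in Mll2-/- H3K4me3 as in E14, and 34.9% of their 1218 bivalent windows were lower in H3K4me3, against 57% of 7439 on other chromosomes. A smaller number of bivalent windows there is argued against, since the gap within bivalent windows was -22.1 points (95% interval -25.0 to -19.2). After division by the chromosome ratios of the H3K27me3 libraries the gap was -3.38 points (-6.4 to -0.37), so more copies of both chromosomes in the Mll2-/- cells may account for most of it. A lower dependence on Mll2 on these chromosomes stays open for the rest, because the gap in FC/FC over F/F was -8.89 points (-11.8 to -5.96), between the values that would argue for it and against it. The intervals of these gaps treat windows of 1 library pair as independent, and say nothing about variation between cultures.

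Windows bivalent in both lines had a median log2 ratio of -0.86 in the E14 pair and -0.55 in the F/F pair, a difference of 0.315. A higher even background in the F/F and FC/FC libraries, taken as the median of 10000 bp bins, is argued against. The difference was 0.318 after it was subtracted. A higher background at the windows themselves was not tested. Fewer reads were examined in 3 tests tried in turn, with the E14 pair thinned to the depth of the F/F pair. The first, the count of lower windows (7492 before, 6599 after, 3434 in the F/F pair), took in windows of all classes and decides nothing here. The second was the difference in medians itself, a measure that hardly depends on depth. It was 0.321 after thinning (0.308 to 0.336 over 100 thinnings), so thinning left this difference in place. As such a measure can hardly move with depth, this outcome was largely fixed in advance and does not decide on fewer reads. The third, the share of tested windows bivalent in both lines that were lower, was 53.9% before, 53.3% after and 36.9% in the F/F pair. It met its limit of 1.5 times before any thinning, so it decides nothing. The cell line and the time since deletion, which differ between the pairs in the labels, may each account for the difference and were not tested.

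A further 13 windows were at least 2-fold changed in opposite directions in the E14 and F/F pairs, a difference that was not tested. Chromosome 1 had 1.44 times the median reads per bin of the GFP libraries in the Cxxc1 library and 1.496 times in the untagged serum control. Chromosome 19 had 1.64 times that median in the N-terminally tagged Mll2 library in serum. In the untagged 2i control the reads per bin on chromosome X were 0.823 of those on autosomes, and chromosome Y held 87 reads. Chromosome Y held 27 reads in the double FC/FC library at day 4 of atRA and 847 in the double FC/FC library at day 0. In the untagged serum control, 2251008 positions were listed exactly 2 times.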

How the results depend on the processing

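Leaving out chromosomes 8 and 11, median-ratio scaling over H3K4me3-only windows, other gaps between transcribed intervals, counting RNA positions once and the comparison with Mll2 FC/FC were chosen after the data were seen. Of the main results, 108 values under alternatives planned in advance stayed within 1.5 times the reported count or within the spread, and 55 did not; for added alternatives the numbers were 21 and 9. For other results they were 35 and 45, and 3 and 1. The spread was the SD between the 2 Mll2 pairs, or between the 2 days for RNA medians. It was 0.119 for differences between class medians, where the value for Mll1-/- over E14 was -0.055. For H3K27me3 medians it was 0.251, where the value for Mll2-/- over E14 was 0.054. Values this small could hardly leave the spread, so their staying within it says little. No difference between bivalent and H3K4me3-only medians changed sign. For counts the direction was not part of this comparison, and the balance did turn in some. Background scaling gave 4469 lower and 4917 higher windows in the double line over E14 at day 4, against 5043 and 2418. For Mll2 loss in RNA, 1 interval fell and 3 rose with a pseudocount of 2, against 6 and 3. With higher read minimums or folds fewer windows can pass; otherwise the cause was not tested.

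Lower H3K4me3 windows with at least 50 reads numbered 3000 in Mll2-/-, 1358 in FC/FC, 145 in Mll1-/-, 1681 in the double line over F/F and 7362 over E14. At day 4 they numbered 2543 in Mll2-/-, 51 in Mll1-/- and 2599 in the double line, at day 7 1554, and 775 in both Mll2 pairs. With at least 10 reads they numbered 5449 in FC/FC, 2609 in Mll1-/- and 12085 in the double line over F/F. At day 4 the counts were 729 in Mll1-/- and 7752 in the double line, and at day 7 4467 in Mll2-/-. Under a 3-fold rule they numbered 4694 in Mll2-/-, 1132 in FC/FC, 223 in Mll1-/-, 3044 in the double line over F/F and 9182 over E14. The counts were 39 in Mll1-/- at day 4, 1866 in Mll2-/- at day 7 and 682 in both pairs. Size factors over H3K4me3-only windows gave 8968 in the double line over E14 and 306 in Mll1-/- at day 4, where background scaling gave 34 and windows of 2000 bp on either side 257. Leaving out either Mll2 pair left 3434 and 7492 lower windows in the other.

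The limma test of H3K4me3 called 0 windows with no block (1466 unadjusted), 0 with no filter (6487 unadjusted) and 6653 with the day 4 and day 7 pairs added. Classes at 5-fold enrichment gave a bivalent minus H3K4me3-only median of -0.88 in Mll2-/- over E14.

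The limma calls for Mll2 loss in RNA numbered 24 with median-ratio scaling, 0 without a trend (3217 unadjusted), 1 with at least 20 reads in 3 libraries, 4 with a pseudocount of 2 and 32 with 2 genotypes. They numbered 415 and 3 with gaps of 300 and 5000 bp, and 3 with positions counted once. For Mll1 loss they numbered 0 without a trend (2463 unadjusted), 69 and 2 with those gaps, and 3 with positions counted once. For atRA they numbered 4292 to 6234 on leaving out a genotype, lowest without Mll2-/-, and 15567 and 3934 with those gaps. Fitting atRA with no replicate block, where the genotype pairs the days, gave 6630. Counts at least 2-fold changed in RNA were 3347 without day 0 and 4953 without day 4 for Mll2 loss, and 4912 and 3234 for Mll1 loss. Median RNA ratios at Mll2-dependent windows were -0.40 at day 0 and -0.22 at day 4 under a 3-fold rule, and 0.0 at day 0 with gaps of 300 bp.

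Against the other untagged control, bound windows numbered 8090 for N-terminally tagged Mll2, 7963 for Cxxc1, 8512 for Ash2l and 10155 for N-terminally tagged Mll2 in 2i. At 5-fold they numbered 10622 for Ash2l, 902 for N-terminally tagged Mll2 in 2i and 12166 for the C-terminal tag, and at 2-fold 8085 for N-terminally tagged Mll2 in 2i. Windows with fewer than 20 reads in both libraries were not tested, and with 1 library per group no depth replaces replicates.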

Other observations

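The tests of splits of the RNA libraries, the clusters and the windows named in this part were chosen after the result was seen.

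Some Mll2-dependent windows lay close together. With gaps of at most 50 kb, 23 clusters held 3 or more such windows, while 1896 windows stood alone. On chromosome 13, 22009701 to 22114700, 6 of 7 tested windows were lower in both pairs over 105.0 kb, with median log2 ratios of -2.76 in the E14 pair and -1.21 in the F/F pair. On chromosome 13, 23487301 to 23546700, 6 of 8 were, with medians of -2.80 and -1.22. On chromosome 6, 128709701 to 128794300, all 4 tested windows were lower over 84.6 kb, with medians of -3.27 and -2.60 and a median of 0.02 in Mll1-/- over E14.

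Some windows were higher in both Mll2-/- and Mll1-/- than in the E14 library that both share as control, and had few reads in F/F and FC/FC. At chromosome 17, 24776701 to 24778700, there were 16 reads in E14, 244 in Mll2-/- and 201 in Mll1-/-, but 12 in F/F and 9 in FC/FC. At chromosome 11, 34891501 to 34893500, there were 8, 79 and 81 reads, with 5 in F/F and 10 in FC/FC. At chromosome 3, 129363301 to 129365300, there were 4, 84 and 46, with 4 in F/F and 7 in FC/FC. The last of these had 0 reads in E14 at day 4, 69 in Mll2-/- and 29 in Mll1-/-. In the double FC/FC library at day 4 the 3 windows had 53, 28 and 42 reads, against 7, 1 and 0 in E14 at day 4.

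The double FC/FC libraries of day 0 and day 4 differed at several windows. Chromosome 2, 124435301 to 124437300, had 1 read at day 0 and 223 at day 4. Chromosome 11, 87261701 to 87263700, had 99 reads at day 0 and 1 at day 4, with 90 in F/F and 3 in E14 at day 0. The ratio of chromosome X to autosomes was 0.431 at day 0 and 0.259 at day 4.

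For atRA, 1 of the 10 splits of the 6 RNA libraries into 3 and 3, the real one, gave as many calls. It gave 8507 and the highest of the others gave 0, which are too few splits for a share under 0.05.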
